A study of Mus musculus with 7 samples.

How the data were processed

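The series holds 7 microarrays of mouse uterus, 1 for each of 7 groups. Per the labels' protocols, C57BL/6 females aged 10 to 11 weeks had their ovaries removed and were killed 7 days later. They received dihydrotestosterone (DHT), an androgen that is not converted to estrogen, at 0.1 mg per mouse under the skin 1, 3, 6, 12, 18 or 24 h before death, or the vehicle 24 h before death. Adhering tissue was removed from the uteri, which were frozen and extracted with Trizol, and 20 µg of pooled RNA was labelled for the Affymetrix U74Av2 array. The protocols name 10 mice without saying whether that number went into each pool. The design text of the series lists a 0.5 h group and no 18 h group, while the array titles list 18 h and no 0.5 h, and the titles were followed. Lights went on at 07:15 for 12 h a day, and the hour of death is not given.

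The deposited values are signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, which give no version, and detection calls were not used here. Tested on the values, every array had a mean of 499.9 over the central 2 to 98 percent of its probe sets, so the arrays had been scaled to a common target, and this scaling was kept. The medians of the 7 arrays lay between 227.4 and 237.0. The table holds 12488 probe sets, of which 66 are the maker's controls and were kept out of counts and tests. Gene symbols came from the table that pairs the array's probe sets with genes. Of the other 12422 probe sets, 10833 named 1 gene, 396 named several and 1193 named none. No coordinates are given, and the gene table of assembly GRCm38.p6 served only to check names.

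Signals under the 40th percentile of all values, 145.9, were raised to that value, here called the floor, and log2 was taken. Between 39.4 and 40.8 percent of the values of an array lay under the floor. Probe sets with a mean log2 above the floor were kept for tests, 8421 in all. A gene was represented by its brightest probe set among those that named 1 gene, which gave 6326 genes. With arrays, their number limits the precision of every value.

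With 1 array per group, single times were described and not tested. For each time the probe sets at least 2-fold above or below vehicle were counted where the higher signal was at least 291.8, and the same count was made for all 21 pairs of arrays. For 35 gene lists, 23 of pathways and 12 of cell type markers, the median log2 ratio to vehicle was given with its percentile among 10000 random lists of the same size matched on expression in 20 bins. The random lists hold unrelated genes, so their range takes no account of genes in a list that move together. In a simulation with independent noise, 10 of 198 pairs of list and time lay outside its central 95 percent, besides 1 planted pair. Lists with fewer than 5 genes above the filter have gene values only.

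For tests the DHT arrays were joined into early (1, 3 and 6 h) and late (12, 18 and 24 h), 3 arrays each, and limma compared early with vehicle, late with vehicle and late with early, with a variance trend on expression, 4 residual degrees of freedom and a prior of 1.69. The spread comes from arrays at different times within a phase, and the lone vehicle array is assumed to vary like the others, so anything particular to that array counts as treatment. Tests were two-sided and adjusted by Benjamini-Hochberg at 0.05 over 8421 probe sets. The lists were tested with limma's camera at the preset correlation of 0.01, adjusted over 33 lists within each contrast, and again with an estimated correlation. With an estimated correlation camera judges each list on the 4 residual degrees of freedom. Few lists can then pass, so a call lost there does not show that the correlation between genes removed it. Whether arrays close in time were alike was tested with the Spearman correlation between the difference in time rank and 1 minus Pearson's r over 21 pairs, with an exact two-sided permutation of the time labels in 5040 orders. Vehicle was ranked ahead of 1 h, as its title gives 0 h, although it was taken 24 h after its injection. The ratios of 3 prime to 5 prime control signals served as a measure of RNA quality.

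Named genes followed a rule. It takes the 6 highest and 6 lowest in each phase among genes of the same sign at all 3 times and at least 2-fold at 2 neighbouring times, and the 4 highest and 4 lowest at each time where a neighbouring time had the same sign and a size of at least 0.5. It adds the 5 lowest p in each direction for late against early, since none passed, the list of ATM, Gadd45 and p53 damage signalling, which the series title points to, and list members at least 2-fold at 2 or more times. It ends with the 4 largest bounds in each direction among genes at the floor on vehicle and on none of the late arrays, or the reverse. The groups, tests, lists, alternatives and this rule were chosen before the data were examined.

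Alternatives changed the floor to the 20th or 60th percentile, the scaling to quantile normalization or median centring, the log2 step to a pseudocount of 16 without a floor, the threshold to 1.5-fold or 3-fold, the reference to the 1 h array, the variance trend to none, the phases to a straight line over time rank, the brightest probe set to the mean of a gene's probe sets, and the correlation between arrays to Spearman's, dropped the filter on low signals or the minimum on the higher signal, and left out each array in turn. A fit without a floor and one with the opposite-strand control signal as a covariate were chosen after seeing the data. On simulated data with a planted log2 change of 1 in 200 probe sets, the contrast of late with early recovered 77.5 percent with 11 false calls. That of late with vehicle recovered 39.5 percent with 4 false calls. The simulated noise was independent between genes and arrays and had no floor, so these shares need not hold for the real arrays. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.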

Results

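In the uterus of ovariectomized mice, groups of genes were highest at different times after DHT. The DNA damage gene Gadd45g and the immediate early genes were high at 1 and 3 h. Heat shock genes were high at 1 to 12 h, ER chaperones at all 6 times, though barely at 1 h, and genes of ribosome production from 3 h on. ER chaperones and ribosome genes were highest at 6 and 12 h. Mitosis and matrix genes were high at 12 to 24 h, DNA replication genes at 12 and 18 h, and smooth muscle genes at 18 and 24 h. These times describe single arrays. The only vehicle pool was taken 24 h after its injection. At 1 to 18 h, effects of DHT and of the injection itself therefore cannot be told apart. With all arrays and the filter, the immediate early and ER chaperone lists passed neither test against vehicle. No list kept its call with an estimated correlation between genes, a setting in which few lists can pass with so few arrays. Each time had 1 array of pooled RNA and no replicates, so single times were described against the lone vehicle array. Tests compared the 3 early arrays (1, 3 and 6 h) and the 3 late arrays (12, 18 and 24 h).

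The number of probe sets at least 2-fold from vehicle was highest in the middle of the series. It was 95 at 1 h (46 higher and 49 lower), 169 at 3 h (99 and 70), 206 at 6 h (105 and 101), 264 at 12 h (147 and 117), 203 at 18 h (114 and 89) and 162 at 24 h (79 and 83). These counts depended on the floor and the threshold. At 12 h the count was 866 with a floor at the 20th percentile, 121 with one at the 60th, 1133 at 1.5-fold and 37 at 3-fold. The pair of DHT arrays least apart was 6 h with 12 h, with 63 probe sets at least 2-fold apart, and the pair most apart was 3 h with 12 h, with 266. Control probe sets for the opposite strand of actin and Gapdh were likewise close at 6 and 12 h (mean log2 ratios to vehicle of -1.02 and -1.23) and far apart at 3 and 12 h (0.32 and -1.23). With vehicle ranked ahead of 1 h, arrays close in time were more alike. The Spearman correlation was 0.563 between time rank difference and 1 minus Pearson's r over the 21 pairs of arrays (exact two-sided permutation p = 0.0278). Without the 6 h array it was 0.387 (exact p = 0.150). With fewer pairs left, it was 0.516 without vehicle (exact p = 0.0611), 0.528 without 1 h (exact p = 0.0639), 0.483 without 3 h (exact p = 0.0750) and 0.515 without 12 h (exact p = 0.0639). Without 24 h it was 0.747 (exact p = 0.0139). Where a gene had 2 or more probe sets above the floor and the first in table order was at least 2-fold from vehicle, the last had the same sign for 4 of 4 genes at 1 h, 6 of 8 at 3 h, 10 of 18 at 6 h, 21 of 22 at 12 h, 12 of 12 at 18 h and 3 of 8 at 24 h. Over all genes with 2 or more such probe sets the log2 ratios of the first and last had a Pearson correlation across genes, which are not independent replicates, of 0.02, 0.16, 0.21, 0.31, 0.27 and 0.19 in time order.

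**Figure D1:**
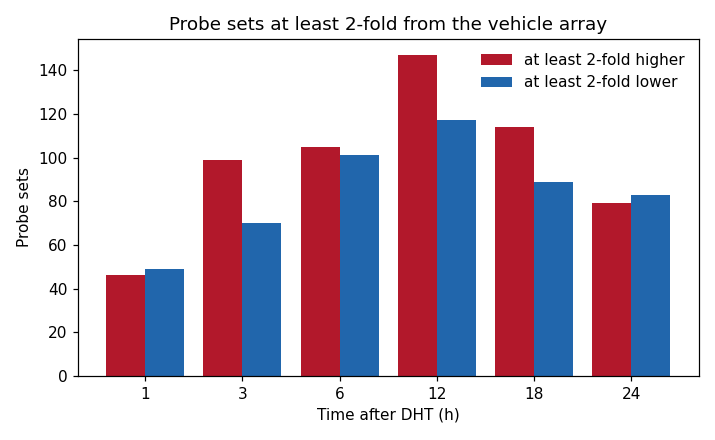
Number of probe sets at least 2-fold higher or lower than on the vehicle array at each time after DHT, 1 array per time. The totals went from 95 at 1 h to 264 at 12 h and 162 at 24 h.

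The series title points to ATM and Gadd45g signalling after DHT. Gadd45g, a stress sensor that slows the cell cycle and acts on MAP kinases, was the gene with the highest ratio to vehicle at 1 h and at 3 h among the genes eligible at those times. Its signal was 435.4 on vehicle, and its log2 ratio to vehicle was 1.77 at 1 h, 2.87 at 3 h, 0.86 at 6 h and -0.70 at 18 h. The related damage gene Gadd45a was 0.78 and 0.79 at 1 and 3 h and -0.71 at 18 h. Gadd45b, the other member of the family, was at the floor on vehicle and 0.85 above it at 3 h, a lower bound, while its other probe set was at the floor from 3 h on. Atm, the kinase that senses double strand breaks, lay between -0.45 at 3 h and 0.46 at 6 h, with no common sign across the times. Cdkn1a, which encodes the cell cycle inhibitor p21, was 0.73, 0.87, 0.80 and 0.68 at 1 to 12 h and -0.48 at 24 h on its brighter probe set. The other Cdkn1a probe set gave 0.04, 0.00, 0.35 and 0.14 at 1 to 12 h and 0.34 at 24 h. H2ax, the histone variant marked at breaks, was 0.87 at 18 h, the phosphatase gene Cdc25c, which starts mitosis, was 1.41 at 18 h, and the epithelial damage gene Sfn was 1.06 at 3 h. Ccng2, a cyclin gene of arrested cells, was lower at all 6 times, down to -0.81 at 3 h.

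As a group, the 30 genes for ATM, Gadd45 and p53 damage signalling did not pass a test, although their median was above the range of random lists at 4 of the 6 times. Lying outside that range was common, as 76 of 198 pairs of list and time did so. The median log2 ratio was 0.17 at 1 h, 0.00 at 3 h, 0.21 at 6 h, 0.22 at 12 h, 0.26 at 18 h and 0.04 at 24 h, at percentile 99.7, 57.6, 99.7, 99.3, 99.97 and 80.2 of matched random lists. Among its members, 20 lay above vehicle in the early mean and 20 in the late mean. In limma's camera the list passed in none of the 3 contrasts (adjusted p = 0.243 for early against vehicle, 0.131 for late against vehicle and 0.544 for late against early). Gadd45g itself was lower in the late than in the early mean (log2 difference -2.18 ± 0.52 SE), which missed the threshold in limma (adjusted p = 0.295).

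**Figure D2:**
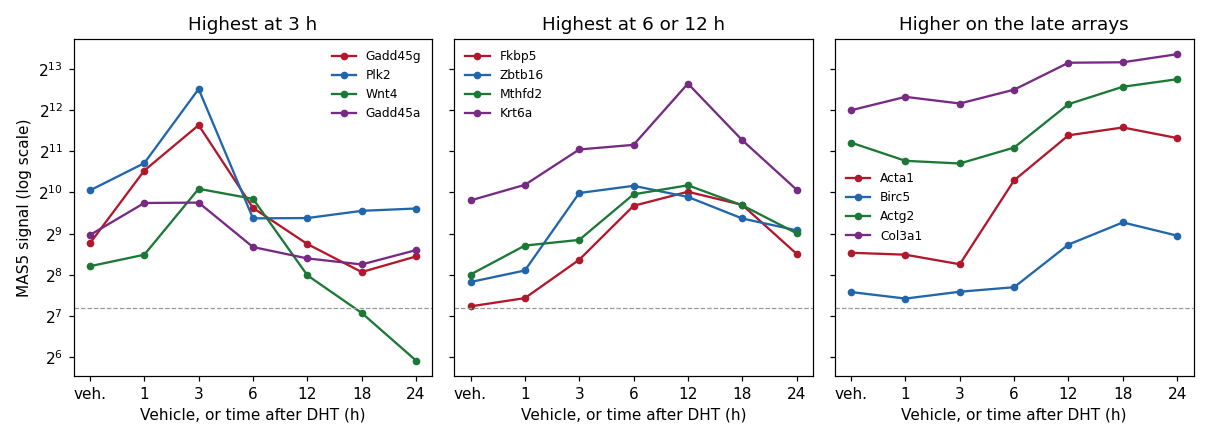
MAS5 signal on a log axis against hours after DHT for 12 genes in 3 panels, 1 array per point, with the floor of 145.9 as a dashed line. Gadd45g and Plk2 were highest at 3 h, Fkbp5 at 12 h, and Acta1 and Birc5 at 18 h.

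On the 3 h array several response genes were at their highest. That array also had 12 probe sets at least 2-fold from all 6 other arrays, the most of any array, and its spike-in controls were 0.57 above vehicle on the log2 scale, against 0.45 at 24 h. Plk2, a kinase gene of early response, was 0.66 at 1 h, 2.46 at 3 h and -0.68 at 6 h. Padi1, which encodes an enzyme that turns arginine into citrulline and follows estrogen in the uterus, was 1.96 at 3 h. Wnt4, a secreted signal that uterine stroma needs to decidualize, was 1.88 at 3 h and 1.64 at 6 h and then at the floor at 18 and 24 h, at least 1.02 below vehicle on the log2 scale. Vegfa, the main growth factor of vessels, was 0.89, 1.63 and 1.36 at 1, 3 and 6 h. Also high at 3 h were Adm (1.92), a peptide that widens vessels, Inhbb (1.79, a bound, as it was at the floor on vehicle), an activin subunit gene, and the stress genes Errfi1 (1.82), Ier3 (1.65) and Fos (1.42). These 5 genes were chosen after their values were seen. No vehicle pool was taken 3 h after injection, so for the genes high on this array DHT and the injection cannot be told apart. Among 24 genes of the uterine estrogen response, 6 were at least 2-fold higher at 3 h, with a list median of 0.20 at percentile 99.8. The estrogen list did not pass in camera (adjusted p = 0.483, 0.571 and 0.0718 in the 3 contrasts). For late against early, 3 of its genes were lower when adjusted over the list alone and 0 over all genes tested in limma (5 at an unadjusted p under 0.05).

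The 21 immediate early genes had a median of 0.25 at 1 h and 0.38 at 3 h and lay at or below -0.06 afterwards, and 5 of them were at least 2-fold higher at 3 h. They fell from the early to the late phase (median difference -0.34, 18 of 21 below 0, adjusted p = 3.26e-05). For them the adjusted p = 0.388 with an estimated correlation. Against vehicle they passed neither early (adjusted p = 0.243) nor late (adjusted p = 0.136). Without the filter on low signals the late contrast did pass, at a median difference of -0.17. Ccn2, a matrix-linked growth factor of this list, was -1.27 at 12 h and -1.55 at 18 h. The TGF-beta, BMP, Wnt and uterine patterning genes fell as well (median difference -0.20, 20 of 28 below 0, adjusted p = 0.00313), with adjusted p = 0.291 with an estimated correlation. The phosphatases of MAP kinases and tyrosine kinases fell by a median of 0.19 on the log2 scale (11 of 14 below 0, adjusted p = 0.0248), and adjusted p = 0.312 with an estimated correlation. That call was lost without the 24 h array (adjusted p = 0.103) and without the 3 h array (adjusted p = 0.0597).

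The androgen and glucocorticoid receptors share many DNA sites, and a few genes that answer to both were high from 3 h on, while the list of glucocorticoid-response genes was high at 1 to 12 h. Zbtb16, a zinc finger repressor induced by steroids, was 0.28 at 1 h, 2.16 at 3 h, 2.34 at 6 h, 2.07 at 12 h, 1.54 at 18 h and 1.25 at 24 h. Fkbp5, a receptor co-chaperone, was 1.13 at 3 h, 2.44 at 6 h, 2.78 at 12 h and 1.28 at 24 h from a vehicle signal of 150.5, just over the floor. Hsd11b2, whose enzyme inactivates corticosterone, was -0.91 at 1 h and 1.67 at 6 h. The 21 glucocorticoid-response genes had medians of 0.37, 0.49, 0.28 and 0.27 at 1 to 12 h, 0.06 at 18 h and 0.11 at 24 h, the last 2 inside the range of random lists. They rose in the early phase against vehicle (median difference 0.34, 17 of 21 above 0, adjusted p = 0.000323), and adjusted p = 0.708 with an estimated correlation. From early to late they fell (median difference -0.21, 14 of 21 below 0, adjusted p = 0.0103), with adjusted p = 0.291 with an estimated correlation and adjusted p = 0.0597 without the 3 h array. The 13 androgen-response genes had medians of 0.13, 0.19 and 0.21 at 1, 3 and 6 h and of 0.03, -0.06 and 0.04 at 12, 18 and 24 h, and passed in no contrast (adjusted p = 0.101, 0.612 and 0.139). Within that list Igfbp3, a carrier of insulin-like growth factors, was -1.55 at 12 h and -1.88 at 18 h, and Sat1, an enzyme of polyamine breakdown, was -1.15 at 6 h and at 12 h.

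Genes for protein folding and ribosome production had their highest medians at 6 or 12 h. The 14 heat shock genes had medians of 0.46, 0.66 and 0.58 at 3, 6 and 12 h and of 0.18 and 0.20 at 18 and 24 h, the last 2 inside the range of random lists, and Hsph1, a co-chaperone of the HSP70 system, was 1.61 at 6 h. They rose in the early phase (median difference 0.48, 12 of 14 above 0, adjusted p = 0.000108), and adjusted p = 0.726 with an estimated correlation. In the late phase they rose by 0.34 (13 of 14 above 0, adjusted p = 0.0158), with adjusted p = 0.698 with an estimated correlation and adjusted p = 0.0850 without the 12 h array. Nucleolus and ribosome genes had medians of 0.25, 0.57, 0.48, 0.33 and 0.20 at 3 to 24 h, all above the range of random lists. At 6 h their median was highest, with the helicase gene Ddx21 at 1.52 and Nop56, of the snoRNA complex, at 1.21. They rose early (median difference 0.35, 20 of 21 above 0, adjusted p = 0.000323), with adjusted p = 0.726 with an estimated correlation. Late, they rose by 0.34 (19 of 21 above 0, adjusted p = 0.00758), with adjusted p = 0.620 with an estimated correlation. Late against early, neither the heat shock genes (adjusted p = 0.217) nor the ribosome genes (adjusted p = 0.712) passed. Srm, an enzyme of polyamine synthesis, was 1.83 at 6 h, and Mthfd2, the mitochondrial folate enzyme of growing cells, was 1.95 at 6 h and 2.17 at 12 h. The 16 genes for ER chaperones and the unfolded protein response had a median of 0.12 at 1 h, just above the central range of matched random lists. Their medians were 0.32, 0.69, 0.77, 0.33 and 0.26 at 3 to 24 h, all above that range. At 6 h Manf, a secreted ER stress factor, was 1.66 and the ER chaperone gene Hspa5 was 1.13. Even so, camera did not call the ER list (adjusted p = 0.101, 0.136 and 0.924). Without the 1 h array it was called higher early against vehicle, at a median difference of 0.55.

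At 12 h the keratin gene Krt6a, typical of dividing stratified epithelium, reached 2.84, and its other probe set 3.11. It was 1.24 at 3 h, 1.46 at 18 h and 0.26 at 24 h. Krt13, another keratin of stratified epithelium chosen after its values were seen, was 1.64 at 12 h. The late-against-early difference of Krt6a missed the threshold in limma (adjusted p = 0.813).

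**Figure D3:**
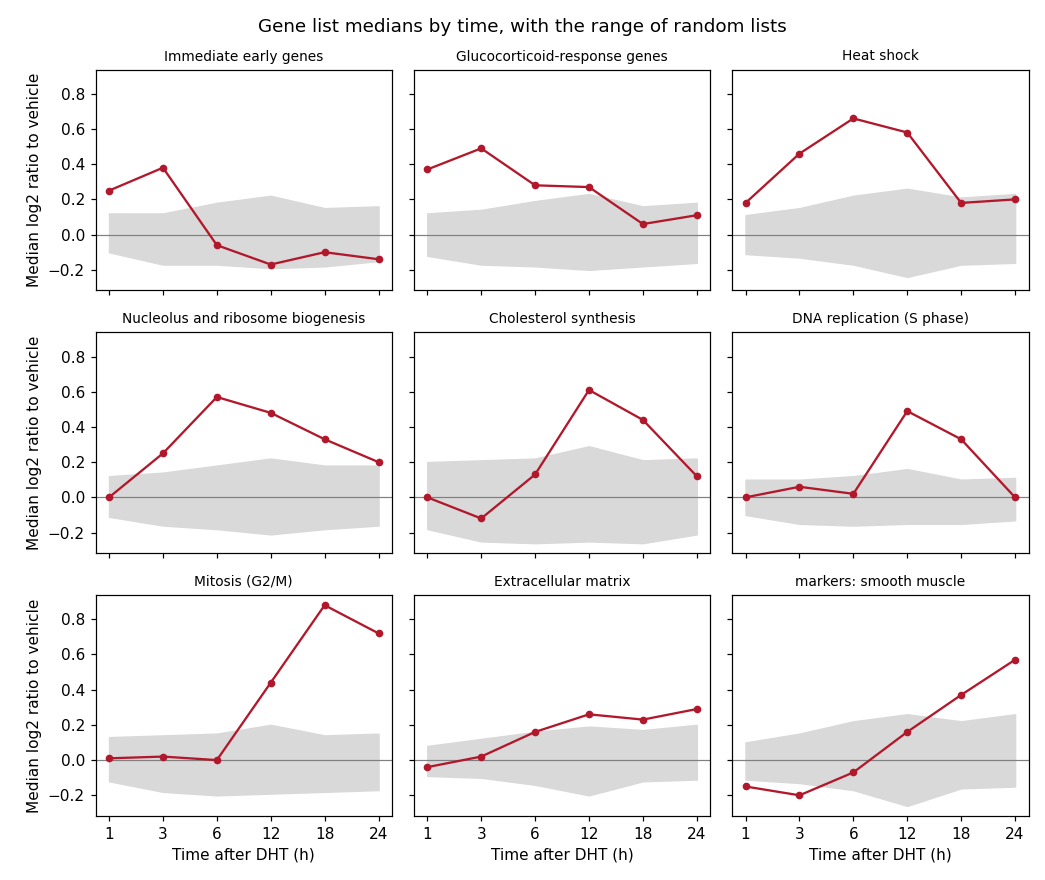
Median log2 ratio to vehicle of 9 gene lists against hours after DHT, with the central 95 percent of matched random lists in grey. The immediate early genes left that range at 1 and 3 h, heat shock genes at 1 to 12 h, and mitosis genes at 12 to 24 h, with a highest median of 0.88 at 18 h. Over all lists, 76 of 198 pairs of list and time lay outside that range.

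The late phase was marked by genes of cell division. The 28 mitosis genes had medians of 0.01, 0.02 and 0.00 at 1, 3 and 6 h and 0.44, 0.88 and 0.72 at 12, 18 and 24 h. At 18 h 13 of them were at least 2-fold higher. They rose from the early to the late phase (median difference 0.66, 28 of 28 above 0, adjusted p = 6.05e-20), and adjusted p = 0.291 with an estimated correlation. Of these genes 19 were higher when adjusted over the list alone and 0 over all genes tested in limma (20 at an unadjusted p under 0.05). Against vehicle the list rose by 0.72 (27 of 28 above 0, adjusted p = 4.02e-12), with adjusted p = 0.457 with an estimated correlation, and 9 genes passed when adjusted over the list alone. Birc5, which encodes survivin of the chromosomal passenger complex, was 1.15, 1.69 and 1.37 at 12, 18 and 24 h. Its late-minus-early difference was 1.42 ± 0.17 SE (adjusted p = 0.174 in limma). Aurkb, the kinase of the same complex, was at the floor on vehicle and at least 3.31-fold higher in the late mean. Kif20a, a kinesin of cytokinesis, was at the floor on vehicle and at 1 and 3 h, so its difference of 1.06 between late and early is a lower bound (adjusted p = 0.174 in limma). Cks2, a partner of mitotic kinases, was 1.34 at 18 h and Top2a, which untangles chromosomes, was 1.33. Mki67, the proliferation marker, was 1.40 at 18 h on its brighter probe set, while its other probe set was lower than vehicle at every time.

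The genes of DNA replication came with a peak at 12 h, ahead of the mitosis genes. The medians of the 27 replication genes were 0.02 at 6 h, 0.49 at 12 h, 0.33 at 18 h and 0.00 at 24 h. Rrm1, a subunit of the enzyme that makes deoxynucleotides, was 1.33 at 12 h and 1.44 at 18 h. The replication factor genes Mcm3 (1.17) and Pcna (0.93), chosen after their values were seen, were highest at 12 h. Replication genes rose from early to late (median difference 0.22, 24 of 27 above 0, adjusted p = 7.02e-05), with adjusted p = 0.450 with an estimated correlation. In that contrast 1 gene was higher when adjusted over the list alone and 0 over all genes tested in limma (7 at an unadjusted p under 0.05). Against vehicle they rose by 0.28 (24 of 27 above 0, adjusted p = 0.000789), with adjusted p = 0.583 with an estimated correlation. Cholesterol synthesis genes had medians of 0.61 at 12 h and 0.44 at 18 h. Fdps, which makes farnesyl diphosphate, was 1.37 and 1.54, and Idi1, the isomerase ahead of it, was at the floor on vehicle and at least 1.98 higher at 12 h. The cholesterol list rose from early to late (median difference 0.39, 11 of 13 above 0, adjusted p = 0.00211), with adjusted p = 0.291 with an estimated correlation. Against vehicle it rose by 0.48 (11 of 13 above 0, adjusted p = 0.0179), and adjusted p = 0.514 with an estimated correlation. The latter call was lost without the 18 h array (adjusted p = 0.0679) and without the filter on low signals (adjusted p = 0.0509), and 1 gene passed when adjusted over the list alone.

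Muscle and matrix genes also rose late. Acta1, the actin of skeletal muscle that smooth muscle expresses at low levels, was -0.05 and -0.28 at 1 and 3 h, 1.76 at 6 h, 2.85 at 12 h, 3.04 at 18 h and 2.79 at 24 h. Its signal on vehicle was 371.0, and its late-minus-vehicle difference missed the threshold in limma (adjusted p = 0.284). The list of skeletal muscle markers, which includes Acta1, passed in no contrast of camera. Late against vehicle it had a median of -0.18, a mean of 0.11 and adjusted p = 0.612, with 0.170 for early against vehicle. Late against early its median difference was 0.09 (9 of 11 above 0, adjusted p = 0.176). Actg2, the actin of visceral smooth muscle, was -0.44, -0.51 and -0.12 at the early times and 0.93, 1.36 and 1.54 at the late ones, a difference of 1.63 ± 0.19 SE (adjusted p = 0.174 in limma). The 12 smooth muscle markers had medians of -0.15, -0.20 and -0.07 at the early times and 0.16, 0.37 and 0.57 at the late ones. They rose from early to late (median difference 0.44, 12 of 12 above 0, adjusted p = 1.52e-10), with adjusted p = 0.291 with an estimated correlation. Of them 11 passed when adjusted over the list alone and 0 over all genes tested in limma (11 at an unadjusted p under 0.05). Against vehicle they rose by 0.39 (11 of 12 above 0, adjusted p = 0.000217), with adjusted p = 0.514 with an estimated correlation and 2 genes passing when adjusted over the list alone.

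Extracellular matrix genes rose late against vehicle (median difference 0.25, 17 of 24 above 0, adjusted p = 0.000217) and against early (0.25, 20 of 24 above 0, adjusted p = 7.57e-06). The former had adjusted p = 0.469 with an estimated correlation and the latter adjusted p = 0.291 with an estimated correlation. When adjusted over the list alone, 5 genes were higher in each contrast and 1 was lower in late against early, with 0 over all genes tested in limma (8 higher and 5 higher at an unadjusted p under 0.05). Col3a1 was 1.15, 1.17 and 1.36 at 12, 18 and 24 h, Col1a1 was 1.01, 1.37 and 1.30 (-0.21, 1.31 and 0.36 on its other probe set), and Sparc, a collagen-binding protein, was 1.11, 1.08 and 1.24. Of the fibrillar collagens, Col5a2 had a late-minus-early difference of 0.92 ± 0.09 SE, and Vcan, the large proteoglycan of loose matrix, one of 0.90 ± 0.10 SE (both adjusted p = 0.174 in limma). Sprr1a, a protein of the cornified envelope, differed by 0.89 ± 0.09 SE (adjusted p = 0.174). Stroma markers rose against vehicle (median difference 0.34, 10 of 14 above 0, adjusted p = 0.0179) and stood at adjusted p = 0.243 early and 0.0541 for late against early. Their late rise had adjusted p = 0.457 with an estimated correlation and 0.0980 without the 24 h array, and when adjusted over the list alone 4 genes were higher and 2 lower. The stroma list shares genes with the matrix list, Col1a1 and Col3a1 among them, so the rises of these lists are not separate results. Epithelium markers lay near vehicle, with medians between -0.05 and 0.13 and adjusted p = 0.780, 0.647 and 0.825.

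In the late phase the marker lists of fat and of macrophages fell, as did the interferon and clock lists. At 24 h, the time at which the vehicle pool had the same interval from injection, the macrophage (-0.02), interferon (-0.09) and clock (-0.15) medians were inside the range of random lists, and the fat median (-0.58) was below it. Some single genes were also lower. In the late mean Igfbp3 was -1.35, Mmp11, a stromal protease, was -1.24, Sec61a2, of the ER translocon, was -1.30 and Kcnj8, a potassium channel of vessel walls, was -1.15. Dio2, which activates thyroid hormone, was 0.43, 0.63 and 0.32 at the early times and -0.45, -1.13 and -1.13 at the late ones, a difference of -1.37 ± 0.21 SE (adjusted p = 0.212 in limma). The MHC class II gene H2-Ab1 differed by -0.60 ± 0.07 SE (adjusted p = 0.174), the water channel gene Aqp1 by -0.67 ± 0.09 SE and the patterning gene Hoxd9 by -0.50 ± 0.07 SE (both adjusted p = 0.212). Macrophage and leukocyte markers fell late against vehicle (median difference -0.21, 14 of 19 below 0, adjusted p = 0.00202) and against early (-0.20, 16 of 19 below 0, adjusted p = 0.000422). For these, adjusted p = 0.514 with an estimated correlation and adjusted p = 0.304 with an estimated correlation, and 4 and 2 genes were lower when adjusted over the list alone. Interferon-induced genes fell late against vehicle (median difference -0.22, 16 of 17 below 0, adjusted p = 0.0149), with adjusted p = 0.514 with an estimated correlation. Their other contrasts had adjusted p = 0.101 and 0.176.

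Circadian clock genes fell late against vehicle (median difference -0.32, 13 of 15 below 0, adjusted p = 0.0179) and against early (-0.35, 11 of 15 below 0, adjusted p = 0.0107). They had adjusted p = 0.457 with an estimated correlation for the former and adjusted p = 0.291 with an estimated correlation for the latter, which was lost without the 3 h array (adjusted p = 0.0597). The clock repressor gene Nr1d1 was -1.56 at 12 h and the clock output gene Dbp was -0.60 at 12 h and 0.96 at 24 h, both chosen after their values were seen. The hour of death of the pools is not given, and the vehicle pool matches the 24 h pool alone in time from injection.

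Fat markers fell in all 3 contrasts, by medians of -0.34 early (10 of 12 below 0, adjusted p = 0.00410), -0.54 late (11 of 12 below 0, adjusted p = 0.000217) and -0.28 late against early (9 of 12 below 0, adjusted p = 0.0243). In that order they had adjusted p = 0.726, 0.457 and 0.394 with an estimated correlation. The late-against-early call was lost without 24 h (adjusted p = 0.165), 6 h (0.0971) or 18 h (0.0662). When adjusted over the list alone 1 fat gene was lower early and 7 late. Car3, abundant in fat cells, was -1.02 at 18 h and -1.13 at 24 h, whereas Lep, the fat hormone leptin, was 1.63 at 1 h and higher at all 6 times. Ovary and oviduct markers were lower early (median difference -0.27, 7 of 8 below 0, adjusted p = 0.00410) and late (-0.28, 6 of 8 below 0, adjusted p = 0.0152). They had adjusted p = 0.726 with an estimated correlation early and adjusted p = 0.514 with an estimated correlation late, and without the filter on low signals 0.0883 and 0.0801. When adjusted over the list alone 2 were lower in each. The medians of both lists were below vehicle at all 6 times, from -0.27 at 1 h to -0.58 at 24 h for fat. Those of ovary and oviduct lay between -0.39 and -0.04. With 1 vehicle pool, more adhering tissue in that pool cannot be told from an effect of DHT in the contrasts against vehicle.

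The remaining lists passed in no contrast of camera. Steroid receptors and enzymes had adjusted p = 0.803, 0.584 and 0.400 in the order early against vehicle, late against vehicle and late against early. In that order IGF signalling had 0.905, 0.356 and 0.148, matrix proteases and inhibitors 0.580, 0.445 and 0.657, inflammatory mediators 0.682, 0.861 and 0.465, and apoptosis genes 0.457, 0.362 and 0.709. Angiogenesis and hypoxia genes had 0.882, 0.584 and 0.567, fatty acid and energy genes 0.580, 0.612 and 0.954, endothelium markers 0.780, 0.584 and 0.712, lymphocyte markers 0.375, 0.216 and 0.712, and markers of eosinophils, neutrophils and mast cells 0.847, 0.584 and 0.217. Blood and mesothelium had too few genes for a list. Of the blood markers, Hba-a1 lay between -0.11 and 0.44, Hbb-b2 between -0.09 and 0.72 and Slc4a1 between -0.60 and -0.13. Of the mesothelium markers, Upk3b lay between -0.66 and -0.40, Wt1 between -0.49 and -0.14, Igfbp6 between -0.45 and 0.14 and Rspo1 between -0.05 and 0.24. In all, 17 of 33 lists were called in at least 1 contrast at the preset correlation. With an estimated correlation none was, the lowest adjusted p being 0.708 early, 0.457 late and 0.291 for late against early. That setting rests on few residual degrees of freedom, so few lists can pass it. Even the mitosis list, late against early, had an unadjusted p = 0.0139 in camera there. The lost calls therefore do not show that correlation between genes removed these results.

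Tested gene by gene, limma called 0 higher and 23 lower probe sets for early against vehicle (210 and 323 at an unadjusted p under 0.05) and 0 higher and 26 lower for late against vehicle (466 and 521). It called 0 for late against early (485 higher and 378 lower at an unadjusted p under 0.05). In 16 of the 23 lower calls and 16 of the 26, all 6 DHT arrays were at the floor, and in the other 7 and 10 at least 1 was above it, with vehicle signals of 189.9 to 320.7. Akap2, which anchors protein kinase A, and the bone matrix gene Ibsp are examples, at least 1.76-fold and 1.72-fold lower in the late phase. With all 6 DHT arrays at the floor the spread within phases is 0 by construction. Such calls on their own therefore do not show a lower level after DHT. None of the 23 or 26 was called with the pseudocount in place of the floor, and limma without the variance trend called 0 in either contrast (240 higher and 301 lower early, and 479 and 506 late, at an unadjusted p under 0.05). The pseudocount fit called 9 higher and 1 lower for late against early. They were Actg2 (1.63), Birc5 (1.34), Col3a1 on 2 probe sets (0.90 and 1.35), Kif22 (1.03), Actc1 (0.97), Col5a2 (0.92), Vcan (0.88) and Sprr1a (0.88), with Dio2 lower (-1.35), at adjusted p between 0.0327 and 0.0397. Against vehicle that fit called 2 higher probe sets in each contrast, 1 without a gene name and 1 of the integrin gene Itgav (2.48 early and 3.05 late), whose brightest probe set lay between -0.24 and 0.07. Both had vehicle signals far under the floor, 52.2 and 25.2, so these differences are set against background.

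Some of the lowest ratios came with shifts in control signals. Control probe sets for the opposite strand of actin and Gapdh had mean log2 ratios to vehicle of 0.04, 0.32, -1.02, -1.23, 0.42 and -0.59 in time order. Several genes dipped at the same times. Both Actb probe sets, for beta-actin, did so, the brighter at -1.93 at 6 h and -1.91 at 12 h and the other at -1.83 and -1.92. By contrast, the 3 prime control signal of beta-actin was 28673 on vehicle, 28928 at 6 h and 27772 at 12 h. Klf13, a transcription factor gene, was -2.67 at 12 h and -0.11 at 18 h, with its other probe set at -0.25 and 0.11. The syndecan gene Sdc4 was -1.97 and -0.13 at the same times. The 3 prime to 5 prime ratios were 1.03 to 1.19 for beta-actin and 0.83 to 0.89 for Gapdh. On the vehicle array 6 probe sets were at least 2-fold below all 6 DHT arrays, among them Nup107 of the nuclear pore (log2 ratios of 1.17 to 1.66) and Hsd3b7 of bile acid synthesis (1.12 to 1.66). The other probe sets of Ift46 and Bud31, also in that group of 6, lay between -0.92 and -0.38 and between 0.13 and 0.34. That of Rab31, in the same group, lay between -0.80 and 0.06.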

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

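The tests of the injection, of the share of muscle wall and of the control signal, and the fit without a floor, were chosen only after the results were seen, while the camera contrasts, the pseudocount and the splits of the arrays were planned.

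The late and early times differed in 12 gene lists, each by limma's camera test of the difference itself at the preset correlation. The lists that were higher late had adjusted p = 6.05e-20 for mitosis, 1.52e-10 for smooth muscle markers, 7.57e-06 for extracellular matrix, 7.02e-05 for DNA replication and 0.00211 for cholesterol synthesis. Those that were lower late had 3.26e-05 for immediate early genes, 0.000422 for macrophage and leukocyte markers, 0.00313 for TGF-beta, BMP and Wnt genes, 0.0103 for glucocorticoid-response genes, 0.0107 for clock genes, 0.0243 for fat markers and 0.0248 for phosphatases. With the correlation estimated from the arrays none of the 12 passed. Few lists can pass in that setting, so these losses do not show that correlation between genes removed the differences. Gene by gene, the late and early phases gave 0 probe sets past the threshold in limma (485 higher and 378 lower at an unadjusted p under 0.05). The highest of the other splits of the 6 DHT arrays into 3 and 3 also gave 0. The 10 splits are too few for a share under 0.05, and with a real count of 0 every split gives as many by construction, so this count decides nothing.

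For 4 named genes with a late-minus-early difference of at least 1 in size, all 3 early arrays lay on one side of vehicle and all 3 late arrays on the other. Actg2 and Dio2 had been named for their low p in late against early, so their tests here are not independent of that choice. The late-minus-early differences of the 4 genes on the log2 scale were 1.63 for Actg2, -1.37 for Dio2, -2.18 for Gadd45g and -2.02 for Wnt4. The last is a bound because Wnt4 was at the floor at 18 and 24 h. Limma's test of each missed the threshold (adjusted p = 0.174, 0.212, 0.295 and 0.295). With the pseudocount in place of the floor Actg2 and Dio2 passed (adjusted p = 0.0327 and 0.0394), as they did without a floor (0.0320 and 0.0379). Among 6326 genes 119 had such opposite signs, where 7 exchangeable arrays would give 90.4, and 8 of the 119 had a difference of at least 1. In all, 968 genes, 15.3 percent, had early and late values that do not overlap, where chance gives 10 percent.

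Control probe sets for 18S ribosomal RNA, outside the comparisons, gave more signal than on the vehicle array at 3 h (mean log2 ratio 1.35) and at 18 h (1.32), against -0.41 at 1 h, -0.68 at 6 h, -1.39 at 12 h and -0.24 at 24 h. Their mean signal was 107.6 on vehicle, under the floor of 145.9, and above it only at 3 h (274.9) and 18 h (269.2), so the ratios are set against background.

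The glucocorticoid-response list was high at 1 to 12 h, and a stress response to the injection itself may contribute. At 24 h, the only time at which vehicle and DHT pools had the same interval from injection, the list median was 0.11, inside the range of random lists, while Fkbp5 was 1.28 and Zbtb16 1.25. No vehicle pool was taken at 1 to 18 h, so injection and DHT cannot be told apart for the list at those times. An effect of DHT through its receptor stays open as the biological explanation and was not tested on its own.

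The smooth muscle markers were higher late, and a larger share of muscle wall in the late pools may contribute. The epithelium markers, which a larger muscle share would lower, had a median late-minus-early difference of -0.010 (SE 0.033, 7 above and 9 below 0). How much of the RNA came from muscle is unknown, so the drop to look for is unknown too, and the share of muscle and expression within muscle cells cannot be told apart. A response of muscle cells to DHT stays open.

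The mitosis list was higher late, and a labelling difference that the opposite-strand controls follow was a candidate explanation. The control was alike, within 0.25, in 2 pairs of an early and a late array, 3 h (0.32) with 18 h (0.42) and 6 h (-1.02) with 12 h (-1.23). Over the 28 genes the late array of the pair was higher by a median of 0.91 (SE 0.11) and 0.52 (SE 0.06), and the median over both pairs was 0.67 (SE 0.07, 28 of 28 genes above 0), against 0.66 for all late and early arrays. In these 2 pairs the rise was thus present with alike control signals. The SE is over genes that move together (estimated correlation 0.21). It does not measure the spread between pools, so how much labelling contributes is not settled. The time of day, the mice in each pool and a response to DHT stay open.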

How the results depend on the processing

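The fit without a floor and the fit with the control signal as a covariate were tests chosen only after the result was seen. The others were planned.

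Counts of probe sets at least 2-fold from vehicle moved with the floor and threshold. At 1, 3, 6, 12, 18 and 24 h they were 619, 788, 770, 866, 792 and 770 with a floor at the 20th percentile and 16, 52, 73, 121, 81 and 53 with one at the 60th. They were 375, 639, 924, 1133, 775 and 718 at 1.5-fold and 12, 32, 22, 37, 30 and 18 at 3-fold. A lower floor admits dimmer probe sets by construction. With quantile normalization, median centring, the pseudocount and the 1 h array as reference every count was within 1.5 times. Without a minimum on the higher signal the counts were identical by construction, since a 2-fold ratio over the floor already meets it.

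Limma's calls moved too, and the cause was not tested. For early against vehicle, 2 higher and 24 lower were called with the floor at the 20th percentile, 0 and 31 at the 60th, 0 and 14 with quantile normalization, 0 and 121 without the filter, 2 and 0 with the pseudocount and also without a floor, and 0 and 0 without the trend or with the covariate. Late against vehicle gave 4 and 27, 7 and 35, 0 and 15, 9 and 128, 2 and 0, 2 and 0, and 0 and 0 in the same order, and 1 and 26 with median centring. Late against early gave 9 and 1 with the pseudocount and without a floor, and 0 and 0 elsewhere, a straight line over time rank included. Leaving out 1 array gave 8 to 55 lower calls early, 0 to 2 higher and 0 to 71 lower late, and 0 to 1 higher for late against early.

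All 30 list calls were lost with an estimated correlation, which gave 0 lists in each contrast. A higher correlation is not the reason for every loss. The clock list's estimate was -0.04, under the preset 0.01, yet its late-against-early adjusted p in camera went from 0.0107 to 0.291. That setting also judges each list on the few residual degrees of freedom, on which few lists can pass. How far this removed calls was not tested. Quantile normalization lost 0, no filter 3, and leaving out an array between 0 and 3. Leaving out an array also added calls. The lists called for late against early then numbered 9 to 17, against 12 with all arrays. Early against vehicle, more lists were called without the 1 h or the 6 h array, the ER chaperones among them without 1 h. The similarity over time lay between 0.387 and 0.747 with an array left out. Of 198 list medians by time 33 moved with the floor at the 20th percentile, 19 with the mean of probe sets, 2 with quantile normalization and 1 with median centring, and 45 of 174 with the floor at the 60th. The IGF list at 18 h turned from -0.26 to 0.01 at the 20th percentile, and the cause was not tested. Of 232 phase means of named genes 29 moved at the 20th percentile and 7 with quantile normalization, and 19 of 44 with the mean of probe sets. Signal over background limits the ratios, since 39.4 to 40.8 percent of an array's values lay under the floor.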

Other observations

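The test of pancreas genes was chosen only after the probe sets had been seen.

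On the 24 h array 7 probe sets were at least 2-fold above the floor and above every other array, and 4 of them belong to digestive enzymes of the pancreas. A probe set of the Amy2 amylase family had a signal of 1052 against at most 158.9 elsewhere, and the trypsinogen gene Prss2 had 451.1 against at most 91.6. Of 23 probe sets for 35 pancreas genes 10 were above the floor and highest on that array, some by little (Zg16 at 172.1 against at most 172.0). The same count over all probe sets was not made. The brightest of the 23, of Pla2g1b, had 1619.6 at 24 h and 2476.4 on vehicle. The colipase gene Clps had 194.6 at 24 h and 310.5 on vehicle, and the insulin gene Ins2 was under the floor on every array.

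The numbers of probe sets at least 2-fold from all 6 other arrays were 6 for vehicle, 4 for 1 h, 12 for 3 h, 4 for 6 h, 6 for 12 h, 5 for 18 h and 7 for 24 h. The bacterial and phage spike-in controls had mean log2 ratios to vehicle of -0.02, 0.57, -0.26, -0.36, 0.11 and 0.45 in time order.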
